A study of Mus musculus with 5 samples.

How the data were processed

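RNA-seq was analysed from 3 libraries of primary adipocytes, isolated from the epididymal fat of 17-week-old wild-type C57BL/6 mice. The labels state that RNA was extracted with trizol and that libraries followed standard Illumina procedures. They do not say whether libraries kept strand, so reads of overlapping and antisense genes cannot be told apart. The 2 bisulfite libraries that the series lists, 1 wild-type and 1 with Dnmt1 deleted in adipocytes, were not analysed here. The values are FPKM, deposited by the authors as 1 table with 1 column per library and no log scale. The submitters' processing notes name Trim Galore 0.5.0, Bismark 0.22.1 and featureCounts, and the builds GRCm38 and mm10, without saying which served the RNA. The program that made the FPKM values is not given in the sources used here. The table's columns have the layout that Cufflinks writes, and its smallest positive value is 6.1e-62, far below what 1 fragment is worth, so fragments were shared between transcripts by an estimate. A listed 0 can therefore be a failed estimate, and values of paralogs and overlapping genes are uncertain.

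FPKM divides by library size and transcript length, so a few abundant genes lower the values of all the others, and a level is a share of the RNA and not an amount per cell. No read counts were given and count tests were not used. Low values were compared between libraries to look for relative depth. Ratios of rows with 1 transcription start, above 0 and under 0.15 FPKM in both libraries were counted in bins of 0.02 log2 units. The commonest ratio between replicates 1 and 3, 1.06, held for 122 of 1263 such rows, and no ratio between replicate 2 and the others held for more than 16 rows, so depth stayed unknown. Each library was matched to its column by the column's name in the sample description. Locus starts in the table count from 0 and are given here counted from 1. Of 23596 rows with a RefSeq symbol, 14312 had the same start as the GRCm38.p6 gene and 14178 the same end.

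The table held 24889 rows with 24330 symbols, after 1 emptied line. For 273 symbols with more than 1 row, 805 rows in all, the row with the highest mean was kept. A further 27 rows carried a calendar date in place of a symbol and were left out of gene lists. No row lay on the mitochondrial chromosome, so the planned list of genes of mitochondrial DNA had no measured member. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Values were put on a log2 scale as log2(FPKM + 0.1), which understates ratios of genes near 0. A gene was called detected at FPKM 1 or more. Errors are SDs over the 3 libraries.

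Before the data were examined, 34 gene lists with 516 genes, 22 gene pairs and 10 cell type differences were fixed, and 491 of the genes were measured, 6 of them under another symbol (Park2, Rab1, Ptrf, Tusc5, Eppin and Epb4.2). The level of a list was the median over its genes in each library. Pair ratios and list differences were formed within each library and tested with an exact two-sided sign-flip permutation, with Benjamini-Hochberg adjustment in each family. For deviations between libraries, log2 values were centred on each library's median over genes with a mean FPKM of 1 or more. A list's median deviation was then set among 10000 random lists of the same size drawn from 20 bins of mean expression, as a description with no p, for 28 lists with at least 5 such genes. Simulated data were made with 50 planted lists of 15 genes among 11993. Lists raised 1.5-fold or 2-fold in replicate 1 passed percentile 97.5 in 100% of cases, and unchanged ones in 0%. The simulated genes varied independently and with less noise than the data. There, log2 differences had an SD of 1.08 and 1.095 between replicate 1 and replicates 2 and 3, and 0.565 between replicates 2 and 3. These rates therefore do not carry over to the observed lists, and shifts under 1.5-fold were not planted.

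The genes named were fixed by a rule. They are all genes of the lists of DNA methyltransferases, DNA demethylation, mitochondrial fission and mitochondrial fusion, the genes of the pairs, the 3 highest and the 1 lowest gene of each other list, the 20 highest genes and the 10 most variable ones with a mean FPKM of 5 or more. Some were left out for length, and Aqp7, Inhbb and Dhh were named after their values were seen. After the data were examined 9 lists were added: spermatid and sperm, spermatocyte, spermatogonium, Sertoli, Leydig, neuron, hepatocyte, exocrine pancreas and gut, and retina. Alternatives covered the pseudocount, the detection threshold, the mean in place of the median, filters on low values, rescaling to TPM, summing rows of a symbol and leaving out each library. Promoter CpG content was not analysed here.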

Results

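The series concerned DNA methylation that depends on Dnmt1, the maintenance DNA methyltransferase, in primary adipocytes from the epididymal fat of 17-week-old C57BL/6 mice. It listed 2 bisulfite libraries, 1 from wild-type mice and 1 from mice lacking Dnmt1 in adipocytes, which were not analysed here, and 3 RNA-seq libraries of wild-type adipocytes, which were. The comparison of genotypes was therefore not made. The question that the analysed data address is which genes the wild-type adipocyte preparation expressed, how the genes of the DNA methylation machinery stood among them, and how far the 3 libraries differed. Values are FPKM (mapped fragments scaled to transcript length and library size) per gene. They gave no read counts, so the depth of each library is unknown and no counting interval can be given. The 3 columns summed to 504178, 488721 and 524092 FPKM in replicates 1, 2 and 3. Of 24889 rows, 12612, 11316 and 11773 reached FPKM 1, a mean of 11900 ± 657 (SD, n = 3), and 5668 were listed at 0 in all 3 libraries. The 10 highest rows held 14.0% ± 1.83 of the summed FPKM.

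The maintenance enzyme Dnmt1 and the de novo enzyme Dnmt3a were expressed at similar moderate levels, and the other de novo enzyme, Dnmt3b, was near the detection threshold. Dnmt1 (chromosome 9, 20907206 to 20959888) stood at 5.60, 5.69 and 7.83 FPKM in replicates 1, 2 and 3, and Dnmt3a (chromosome 12, 3806980 to 3914443) at 5.71, 3.68 and 5.72. Dnmt3b stood at 1.03 ± 0.202 FPKM (SD, n = 3). Dnmt1 exceeded Dnmt3b 5.70-fold, a log2 ratio of 2.51 ± 0.192, and Dnmt3a exceeded Dnmt3b by 2.17 ± 0.141, in 3 of 3 libraries each. With a pseudocount of 1 these log2 ratios were 1.85 and 1.55. Dnmt1 exceeded Dnmt3a in 2 of 3 libraries only, with a mean log2 ratio of 0.34 ± 0.332 (exact sign-flip p = 0.5, n = 3). That mean was 0.53 without replicate 1, 0.21 without replicate 2 and 0.295 without replicate 3. Uhrf1, which brings Dnmt1 to hemimethylated DNA, was 2.27 ± 0.322 log2 units below Dnmt1, at 1.28 ± 0.480 FPKM. Its paralog Uhrf2 reached 13.1 ± 1.02, and Usp7, a deubiquitinase that binds Dnmt1, 21.4 ± 0.844. Zbtb24 stood at 3.37 ± 0.165, Cdca7 at 0.800 ± 0.411 and the chromatin remodeller Hells at 0.556 ± 0.130. Dnmt3l, a cofactor of the de novo enzymes in germ cells, had 0.268 and 0.107 FPKM in replicates 1 and 2 and was listed at 0 in replicate 3. Of the 10 measured genes in this list, 5 reached FPKM 1 in every library.

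The list of DNA demethylation genes had a higher median than the methyltransferase list in each library, a difference that was not tested, with a median of 3.43 ± 0.447 on the log2(FPKM + 0.1) scale against 1.10 ± 0.277 for the methyltransferases and maintenance factors, and 10 of 11 reached FPKM 1 in every library. Among genes with a mean FPKM of at least 1 the medians were closer, at 3.72 and 2.32. Among the TET dioxygenases, which oxidise 5-methylcytosine, Tet3 was the highest at 4.49 ± 0.511 FPKM, Tet2 followed at 1.85 ± 0.360, and Tet1 was near 0 at 0.0659 ± 0.0297. Tet2 was below Tet3 by 1.24 ± 0.230 log2 units, a ratio of -1.24, in 3 of 3 libraries. The ratios over Tet1, 3.56 ± 0.0263 for Tet2 and 4.80 ± 0.209 for Tet3, depended on the pseudocount because Tet1 lay under it, and with a pseudocount of 1 they were 1.42 and 2.36. The glycosylases Tdg and Smug1 stood at 3.97 ± 1.12 and 1.71 ± 0.210, and the cytidine deaminase Apobec1 at 13.4, 7.46 and 12.1 in replicates 1, 2 and 3. The stress-inducible Gadd45g and Gadd45b were the highest of the list, at 209 ± 22.1 and 193 ± 22.6, with Gadd45a at 17.5 ± 9.15. Idh1 and Idh2, which make the 2-oxoglutarate that TET enzymes use, stood at 51.3 ± 28.8 and 53.8 ± 12.7. The median of the demethylation list was set by Apobec1, and the genes above it were the Gadd45 and Idh genes. By mean FPKM the TET enzymes, Tdg and Smug1 all lay below Dnmt1 and Dnmt3a, which stood at 6.37 and 5.035. In replicate 2, however, Dnmt3a at 3.68 FPKM lay below Tdg at 4.62 and Tet3 at 3.91. The list fixed as methyl-CpG readers had a median of 3.06 ± 0.133, with 11 of 12 genes detected in every library. Not all its members read methylated DNA, since Cxxc1 binds unmethylated CpG and Mbd3 does not select methylated CpG. Mbd2 led it at 79.7 ± 12.8 FPKM, followed by Mbd3 at 51.7 ± 6.41 and Cxxc1 at 22.4 ± 4.51, and Mbd4 was lowest at 0.460 ± 0.249.

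**Figure D1:**
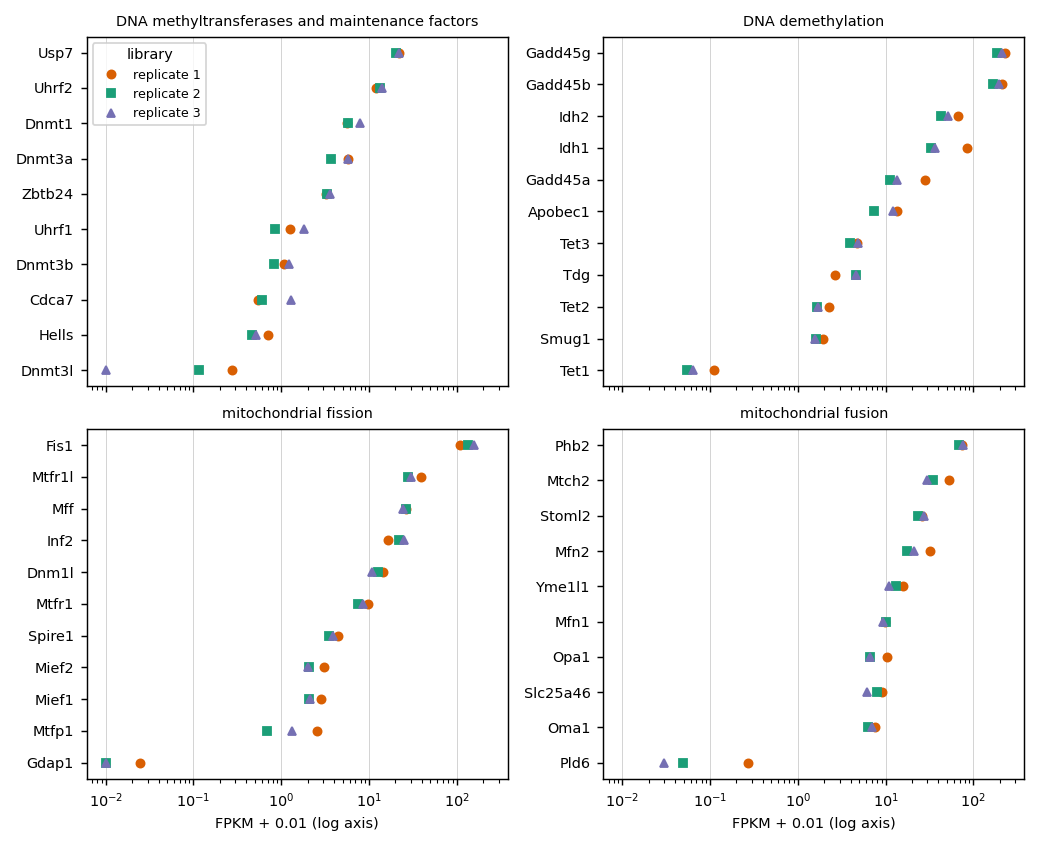
FPKM plus 0.01 on a log axis of each gene of the DNA methylation, DNA demethylation, mitochondrial fission and mitochondrial fusion lists, with 1 point for each of the 3 wild-type libraries. Dnmt1 and Dnmt3a lie close together between 3.68 and 7.83 FPKM, while Tet1 lies at or under 0.0998 in all 3 libraries.

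Genes of mitochondrial fission, fusion and turnover were expressed nearly throughout, with list medians of 3.12 ± 0.185, 3.52 ± 0.169 and 4.71 ± 0.145. In the fission list 9 of 11 genes were detected in every library. Its dynamin Dnm1l stood at 12.7 ± 1.85 FPKM, and its outer membrane adaptors Fis1, Mff, Mief1 and Mief2 at 133 ± 23.5, 25.5 ± 1.21, 2.35 ± 0.425 and 2.37 ± 0.597. Mtfr1l stood at 32.3 ± 5.89, Inf2 at 21.1 ± 4.51, Mtfr1 at 8.61 ± 1.11, Spire1 at 3.93 ± 0.462 and Mtfp1 at 1.52 ± 0.945. Gdap1 was listed at 0 in replicates 2 and 3. In the fusion list 9 of 10 genes were detected in every library. The outer membrane mitofusin Mfn2, at 23.7 ± 7.55 FPKM, was higher than Mfn1, at 9.70 ± 0.412, by 1.24 ± 0.435 log2 units. It was also higher than Dnm1l, by 0.87 ± 0.340. The inner membrane fusion gene Opa1, at 7.90 ± 2.11, was lower than Dnm1l, with a log2 ratio of -0.69 ± 0.213, and each of these ratios had 1 sign in 3 of 3 libraries. Phb2 and Mtch2 stood at 73.2 ± 4.04 and 39.1 ± 12.2, Stoml2 at 25.4 ± 1.93, and the inner membrane proteases Yme1l1 and Oma1 at 13.4 ± 2.39 and 6.93 ± 0.716. Slc25a46 stood at 7.71 ± 1.47 and Pld6 at 0.106 ± 0.134. Sqstm1, Map1lc3b and Pink1 led the mitophagy list at 366 ± 11.7, 158 ± 6.08 and 107 ± 11.9, and Calcoco2 was listed at 0 in all 3 libraries. In the list of RAB8 and vesicle traffic genes, with a median of 4.25 ± 0.184, Rab8a at 33.4 ± 3.85 FPKM was higher than its paralog Rab8b at 16.4 ± 1.59, by 1.02 ± 0.218 log2 units in 3 of 3 libraries. Rab1, Rab11a and Rab10 were the highest of that list, at 58.7 ± 2.84, 52.4 ± 6.30 and 41.5 ± 0.781. The respiratory chain genes encoded in the nucleus were all detected, 22 of 22, with a median of 6.99 ± 0.157. Atp5b, Cox4i1 and Cox6c led them at 540 ± 128, 506 ± 78.8 and 348 ± 51.4.

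Adipocyte genes were among the highest in the preparation and differed by about 3-fold between libraries. Fabp4, the fatty acid-binding protein of fat cells and of capillary endothelium, was the highest gene, at 24050, 40890 and 35480 FPKM in replicates 1, 2 and 3. Of 20 genes in the adipocyte identity list, 19 reached FPKM 1 in every library, and the list median was 7.79, 6.42 and 6.73, a mean of 6.98 ± 0.717. The adipokine genes Adipoq, Retn and Cfd stood at 1476, 1732 and 6288 FPKM in replicate 1, at 432, 407 and 2058 in replicate 2 and at 474, 400.4 and 2194 in replicate 3. Lep, which encodes leptin, was lower than Adipoq by 3.52 ± 0.332 log2 units, and the ratio of Lep to Retn was -3.49 ± 0.135. The list of adipokines and secreted factors had a median of 6.44 ± 0.651 and included Apoe at 2535 ± 271. Fgf21 was listed at 0 in replicate 2. Of the adipogenic transcription factors, Pparg stood at 177 ± 15.2 in all 3 libraries, whereas Cebpa stood at 182, 56.2 and 58.7. Their log2 ratio, Cebpa over Pparg, was accordingly 0.07, -1.78 and -1.48, and its mean of -1.07 ± 0.990 was about as large as the spread (exact sign-flip p = 0.5, n = 3). That mean was -1.63 without replicate 1, -0.71 without replicate 2 and -0.86 without replicate 3. The list of 23 adipocyte transcription factors and corepressors had a median of 4.12 ± 0.160, with every gene detected, and Cebpd stood at 61.7 ± 11.4.

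Lists of lipid and glucose metabolism genes were also highest in replicate 1. The list medians were 6.40, 4.56 and 4.60 for lipolysis, 5.94, 5.06 and 4.38 for fatty acid and triglyceride synthesis, and 5.69, 4.58 and 5.14 for insulin and glucose handling. The triglyceride lipase Pnpla2 was higher than the hormone-sensitive lipase Lipe by 0.49 ± 0.0927 log2 units in 3 of 3 libraries, at 406 ± 221 and 297 ± 182 FPKM, and the monoglyceride lipase Mgll stood at 435 ± 120. Adrb1 was the lowest of the lipolysis list at 0.476 ± 0.411. Dgat2 exceeded Dgat1 by 2.15 ± 0.234 and Scd1 exceeded Scd2 by 6.02 ± 0.877, again in 3 of 3. The insulin-responsive glucose transporter Slc2a4 and the basal transporter Slc2a1 had no common order. Their log2 ratio was 1.36, -0.64 and -1.59, with a mean of -0.29 ± 1.51 (exact sign-flip p = 0.75, n = 3), which became -1.12 without replicate 1, -0.11 without replicate 2 and 0.36 without replicate 3. Cav1 and Ptrf, genes of caveolae, led the insulin and glucose list at 785 ± 34.9 and 571 ± 138, and Irs1 was lowest at 1.46 ± 1.00. Fatty acid oxidation genes had a median of 5.84 ± 0.338, with 15 of 15 detected. Its liver-type carnitine palmitoyltransferase Cpt1a exceeded the muscle-type Cpt1b by 4.46 ± 0.862. Thermogenic genes were low, with a median of -1.25 ± 0.778 and 4 of 16 detected in every library. The uncoupling protein of brown fat, Ucp1, stood at 0.322, 0.0178 and 0.286 FPKM, against 405 ± 82.8 for Ucp2. Cox8b, Ebf2 and Cox7a1 were the highest of that list, at 7.05 ± 5.39, 4.78 ± 1.53 and 4.44 ± 1.36.

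The list medians of endothelial and macrophage genes stood near that of the adipocyte genes. Those of fibroblast and mural cell genes were lower but still high. A list median depends on which genes the list holds, so these levels do not compare amounts of RNA between cell types. The list median was 7.94 ± 0.694 for endothelial genes (14 of 14 detected in every library), 7.04 ± 0.184 for macrophage genes (16 of 16), 5.86 ± 0.458 for preadipocyte and fibroblast genes (16 of 16) and 5.51 ± 0.465 for pericyte and smooth muscle genes (11 of 12). The adipocyte list was above the endothelial list by 0.64 in replicate 1 and below it in the others, with differences of -1.79 and -1.73. The mean of -0.96 ± 1.38 was within the spread (exact sign-flip p = 0.5, n = 3) and became -1.76 without replicate 1, -0.54 without replicate 2 and -0.58 without replicate 3. It was -0.55 with means over members and -0.53 without Fabp5 and Gpihbp1. Against the macrophage list the differences were 0.56, -0.44 and -0.30, and the mean was -0.06 ± 0.541 (exact sign-flip p = 1, n = 3). The mean was -0.37 without replicate 1 and 0.13 without replicate 2. Leading endothelial genes were Gpihbp1, which carries lipoprotein lipase across capillaries, at 651, 1613 and 1425 FPKM, and the tight junction gene Cldn5 at 304, 687 and 526. Leading macrophage genes were Cd74 at 1353 ± 211, Lyz2 at 1003 ± 196 and the complement gene C1qb at 394 ± 15.3, while the macrophage receptor Adgre1 at 31.0 ± 2.27 was below Adipoq by 4.43 ± 0.884 log2 units. Ly6a, Dcn and Col3a1 led the fibroblast list at 575 ± 276, 545 ± 55.1 and 138 ± 61.2, and Col1a1 was below Col3a1, with a log2 ratio of -1.51 ± 0.338. Rgs5, Tagln and Myl9 led the mural list at 227 ± 44.6, 175 ± 122 and 171 ± 93.2.

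The adipocyte list was above each of the other 8 cell type lists in every library. It exceeded the fibroblast list by 2.07, 0.93 and 0.36 log2 units in replicates 1, 2 and 3, and by 0.65 on average without replicate 1. It exceeded the mural list by 1.47 ± 1.08, or 0.85 without replicate 1, the erythroid list by 2.17 ± 1.15, or 1.54 without replicate 1, and the mesothelial list by 4.69 ± 1.37, or 3.93 without replicate 1. Among genes with a mean FPKM of at least 1 the erythroid difference was 0.68. The adipocyte list exceeded the B cell list by 7.49 ± 0.897, the T and NK cell list by 8.20 ± 0.833, the skeletal muscle list by 9.02 ± 0.509 and the list of the epididymis and reproductive tract by 10.28 ± 0.689, each in 3 of 3 libraries. The size of these differences depended on the pseudocount, and with a pseudocount of 1 they were 6.29, 6.54, 6.78 and 6.99. Mesothelial genes were nevertheless all detected, 11 of 11, led by Slpi at 19.6, 57.0 and 74.3 FPKM and Upk3b at 16.1, 27.9 and 65.4. Globin rows were high, with Hbb-b1 at 5840 ± 1809 and Hba-a1 at 4181 ± 429, whereas the erythroid membrane gene Epb4.2 was listed at 0 in replicates 1 and 3. Single globin values are uncertain, since Hbb-b1 and Hbb-bs lie at the same locus in the table and alpha-globin genes are near-identical copies. Of T and B cell genes, Il7r stood at 3.73 ± 1.70, Cd79a at 3.32 ± 1.69 and Cd2 at 1.87 ± 1.15. Of the 18 reproductive tract genes, 9 were listed at 0 in every library, and the highest was Cst8 at 8.61 and 0.246 in replicates 1 and 2 and listed at 0 in replicate 3. The germline list, of genes that DNA methylation silences in somatic tissue or that act in germ cells, had medians of -1.62, -3.32 and -3.32. Mael stood at 10.8 and 0.179 FPKM in replicates 1 and 2 and was listed at 0 in replicate 3, and Sycp3 stood at 4.46, 1.06 and 0.395. Lists of testis cells, added after the data were examined, were highest in replicate 1 along with it. Their medians were 4.24, -0.61 and -1.82 for spermatids and sperm and 0.60, -2.38 and -1.29 for Sertoli cells. For Leydig cells they were 0.00281, -2.996 and -1.92. Of 11 Sertoli genes, 6 reached FPKM 1 in replicate 1, against 2 in replicate 2 and 2 in replicate 3. The highest of them by mean FPKM, Inhbb and Dhh, were however lowest in replicate 1. Inhbb stood at 9.33, 15.2 and 12.0 FPKM in replicates 1, 2 and 3, and Dhh at 1.44, 3.96 and 7.58.

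**Figure D2:**
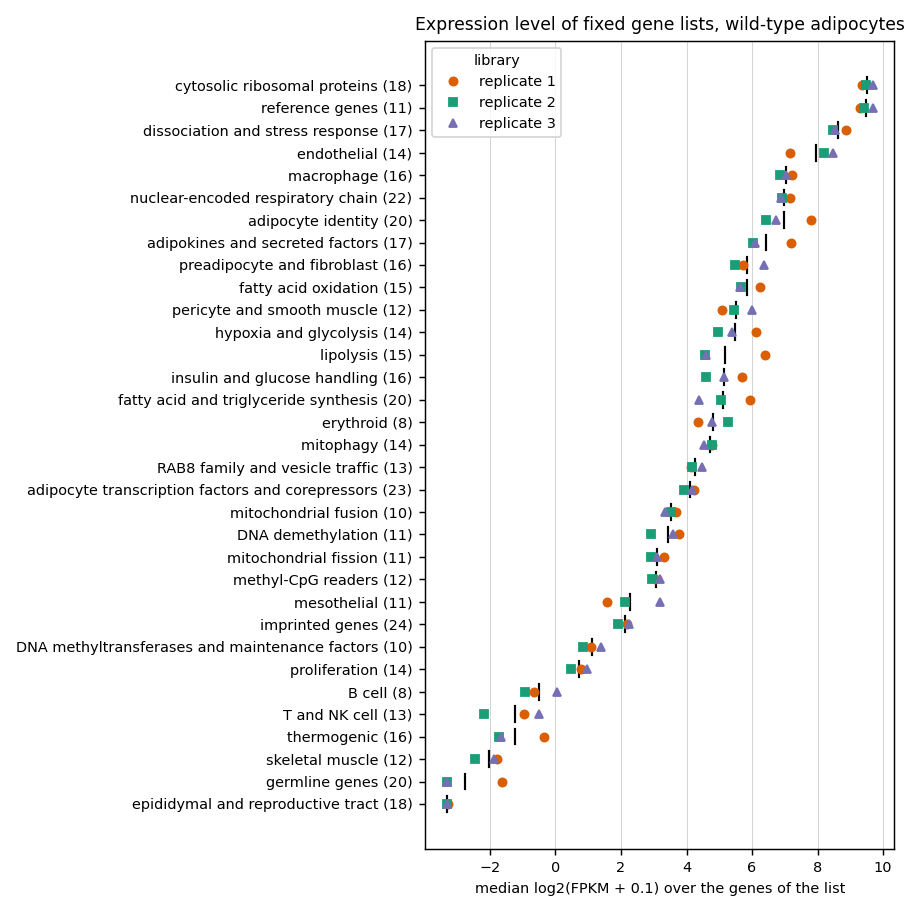
Median log2(FPKM + 0.1) over the measured genes (number in brackets) of each of 33 lists, with 1 point for each of the 3 wild-type libraries and a black bar at their mean. The endothelial list, at a mean of 7.94, and the macrophage list, at 7.04, lie beside the adipocyte identity list, at 6.98, and the germline list stands higher in replicate 1 alone, at -1.62 against -3.32 in the others.

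Immediate-early and stress genes, which tissue dissociation induces, were high in every library, with a list median of 8.63 ± 0.212 and 17 of 17 detected. Fos, Zfp36 and Junb stood at 1427 ± 172, 1394 ± 198 and 1056 ± 107 FPKM. Hypoxia and glycolysis genes had a median of 5.50 ± 0.571, led by Aldoa at 505 ± 71.9 and Ldha at 291 ± 56.3, with Car9 lowest at 0.310 ± 0.115. Proliferation genes were low, with a median of 0.73 ± 0.253, apart from the replication clamp Pcna at 137 ± 6.67. The imprinted list had a median of 2.11 ± 0.170, with 15 of 24 detected in every library. Nnat led it at 685, 93.6 and 182 FPKM, followed by Cdkn1c at 45.4 ± 15.1 and Sgce at 43.0 ± 6.03. Reference genes and cytosolic ribosomal protein genes had medians of 9.47 ± 0.200 and 9.51 ± 0.177, and Eef1a1 and Rps14 stood at 3078 ± 292 and 1262 ± 227. After Fabp4, the highest rows outside the globins included Tmsb4x at 5077 ± 904, the ferritin genes Ftl1 at 4589 ± 343 and Fth1 at 2761 ± 394, and the carbonic anhydrase Car3 at 6835, 2155 and 1528.

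Of the 22 gene pairs, 19 had 1 sign in 3 of 3 libraries, each with an exact two-sided sign-flip p of 0.25, or 0.289 after Benjamini-Hochberg adjustment over the family. Of the 10 cell type differences 8 did, each with an exact p of 0.25, or 0.312 adjusted. With 3 libraries 0.25 is the smallest p that this test can give, so none of the ratios could pass 0.05. Nothing in the labels says that the libraries came from separate animals, so p-values and SDs measure only the spread between these samples, which may be technical.

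Replicate 1 stood apart from the other 2 libraries, with more adipocyte and lipid synthesis RNA and less endothelial and mesothelial RNA. The list medians of testis cells were also higher there. The spermatid and sperm list deviated most, by 3.85 log2 units. It was added after the data were examined, and most of its genes reached a mean FPKM of 1 only through replicate 1. In all, 249 protein-coding genes were more than 8-fold higher in replicate 1 than in both other libraries, against 1 in replicate 2 and 0 in replicate 3. Pearson's r of log2(FPKM + 0.1) across genes was 0.956 between replicates 1 and 2, 0.956 between 1 and 3, and 0.988 between 2 and 3. Of 12069 rows with a mean FPKM of at least 1, 13.3% and 12.9% differed by more than 2-fold between replicate 1 and replicates 2 and 3, against 2.79% between replicates 2 and 3. The median of log2 values over expressed genes was 3.29, 3.08 and 3.25 in replicates 1, 2 and 3, and the deviations that follow are relative to it. The adipocyte identity list lay 1.10 log2 units above the mean of the 3 libraries in replicate 1 and at -0.44 and -0.57 in replicates 2 and 3. Its median gene was 2.90- and 3.11-fold higher in replicate 1 than in replicates 2 and 3. Of its 19 expressed genes, 16 were highest in replicate 1, and Fabp4 and Aqp7, at 24050 and 53.3 FPKM, were lowest there. By uncentred FPKM, 5601 of all 11993 expressed genes (46.7%) were highest in replicate 1. The list of fatty acid and triglyceride synthesis deviated by 1.10 in replicate 1, lipolysis by 0.68, adipokines by 0.61 and insulin and glucose handling by 0.42. The deviation was 0.25 for fatty acid oxidation, 0.24 for the respiratory chain and 0.19 for adipocyte transcription factors. The endothelial list deviated by -0.79 in replicate 1, with 14 of 14 genes lowest there, the mesothelial list by -1.02, the fibroblast list by -0.44 and the mural list by -0.39. The macrophage list deviated by 0.13, and the list of dissociation and stress genes by 0.07 in replicate 1 and -0.11 in replicate 3. In replicate 3 the mesothelial, mural and fibroblast lists lay at 0.86, 0.47 and 0.42, and in replicate 2 the endothelial list lay at 0.45. All of these lay outside the central 95% of 10000 random lists matched on expression in the same library. For the transcription factors this did not hold among genes with a mean FPKM of at least 5, where the deviation was 0.11. Random lists of the same expression can themselves lie off 0. The dissociation and stress list also deviated by 0.07 in replicate 2, but at percentile 28.3, within them. Cytosolic ribosomal protein genes, at -0.24 in replicate 1, lay within them too, at percentile 16.3, although 18 of 18 were lowest there. Counts of genes highest or lowest in a library are therefore a description only.

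The DNA methyltransferase list, with 7 expressed genes, did not lie outside the random lists in any library. It deviated by -0.07, -0.02 and 0.17 in replicates 1, 2 and 3, at percentiles 23.3, 50.85 and 94.9 of matched random lists. Of the 7 genes, 4 were lowest in replicate 1 and 0 were highest there, and Dnmt1 deviated by -0.25, -0.02 and 0.26. Which cells of the mixed preparation these transcripts came from was not tested. The methyl-CpG readers deviated by -0.14, 0.05 and 0.04, DNA demethylation by 0.16, -0.07 and -0.06, and mitochondrial fission by 0.12, -0.03 and -0.09, all within the central 95% of random lists. Among genes with a mean FPKM of at least 5, however, DNA demethylation deviated by 0.31 in replicate 1, outside that range. Without centring, the methyltransferase list deviated by 0.01 in replicate 1. Mitochondrial fusion was at percentile 97.3 in replicate 1 and 1.77 in replicate 3, where it deviated by -0.16. Of 84 combinations of list and library, 42 lay outside that range, where 4.2 would for lists of unrelated genes. Genes of a list can vary together, lists share genes and the 3 libraries' deviations depend on each other, so this is a description only. The 10 most variable genes with a mean FPKM of at least 5 were short RNAs, led by Mir20a at 631 FPKM in replicate 1 and listed at 0 in the others. A row of that length, from 115044157 to 115044263 on chromosome 14, can take a large FPKM from few fragments.

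**Figure D3:**
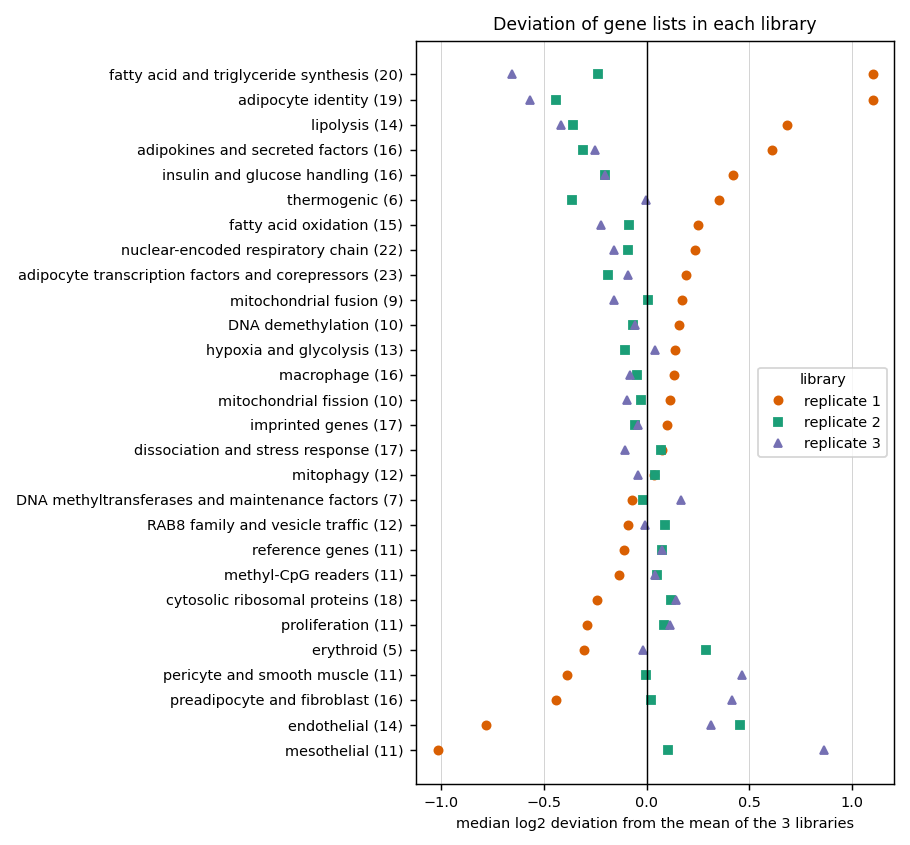
Median deviation, in log2 units, of each list's expressed genes (number in brackets) from the mean of the 3 wild-type libraries after centring, with 1 point per library. Replicate 1 lies at 1.10 for adipocyte identity and at -0.79 and -1.02 for endothelial and mesothelial genes, while the DNA methyltransferase list lies between -0.07 and 0.17 in all 3 libraries.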

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

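The Spearman correlation, the symbols' highest rows and the endothelial list without Fabp5 and Gpihbp1 were chosen after seeing the data, and the other settings before. No ratio, list difference or deviation of replicate 1 that had been called changed its direction under the settings run. The deviations of replicates 2 and 3 were not rerun under other settings. Counting each result under each setting that kept all 3 libraries, pair ratios moved by less than 1 SD in 35 cases and by more in 9, cell type differences in 31 and 9, and list levels in 67 and 63. Leaving out 1 of 3 libraries cannot move a mean by 1 SD and is not counted. The pseudocount moved ratios of genes near it. With a pseudocount of 1 the log2 ratio was 1.85 for Dnmt1 over Dnmt3b, 1.55 for Dnmt3a over Dnmt3b, 1.70 for Dnmt1 over Uhrf1, 1.42 for Tet2 over Tet1, 2.36 for Tet3 over Tet1, -0.95 for Tet2 over Tet3 and 8.38 for Ucp2 over Ucp1. With 0.01, Tet2 over Tet1 was 4.67 and Tet3 over Tet1 5.95. The adipocyte list exceeded low lists by less with a pseudocount of 1, by 6.54 for T and NK cells, 6.29 for B cells, 6.99 for the reproductive tract and 6.78 for skeletal muscle. Among genes with a mean FPKM of 1 or more the differences were 6.24, 5.97 and 5.05 for T and NK cells, B cells and muscle, and 0.68 for erythroid genes. The mean over members gave 8.32 for muscle. Mean Pearson's r between libraries was 0.967, 0.903 among genes with a mean FPKM of 1 or more, and 0.956 to 0.988 when each library was left out. The range was set by replicate 1, without which it was 0.988. The proliferation list deviated by -0.29 in replicate 1, but by -0.062, within the random lists, when values were rescaled to TPM and not centred. The adipocyte transcription factors deviated by 0.11, within the random lists, among genes with a mean FPKM of 5 or more. The cause was not tested. DNA demethylation deviated by 0.31 in replicate 1 among genes with a mean FPKM of 5 or more, and hypoxia and glycolysis by 0.18 there and by 0.14 with a pseudocount of 1, each outside the random lists under those settings only. Values never called changed sign for the adipocyte list minus the macrophage list (0.10 with means over members and among genes with a mean FPKM of 1 or more, 0.13 without replicate 2, 0.06 without replicate 3), for Slc2a4 over Slc2a1 (0.36 without replicate 3) and for the methyltransferase list in replicate 1 (0.01 without centring, 0.02 as TPM). The analysis of promoter CpG content was not run, since it needs a genome sequence not used here, and leaving out mitochondrial DNA genes removes no row. Random lists of genes with a mean FPKM of 1 or more were not drawn for list levels. No paired analysis was possible because only 1 group had RNA-seq libraries. Depth was unknown, so how well values under about 0.1 FPKM, such as those of Tet1, were measured is unknown too.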

Other observations

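The deviations of the adipocyte and endothelial lists were planned, the other tests in this part were chosen after the results were seen, and the genes named here outside the fixed lists were picked by their values. In replicate 1, 249 of 11647 protein-coding genes with a mean FPKM of at least 1 were more than 8-fold higher than in both other libraries, against 1 in replicate 2 and 0 in replicate 3. Among the 249 were 17 of the 19 expressed genes, of 22 measured, of the spermatid and sperm list. That list was added after the data were examined, and most of the 19 reached a mean FPKM of 1 only through replicate 1. The overlap and the fold changes of its median gene were therefore largely fixed by this choice and are only a description. The protamines Prm1 and Prm2, which package sperm DNA, stood at 348, 4.07 and 3.90 FPKM and at 387, 14.2 and 2.92 in replicates 1, 2 and 3, and the transition proteins Tnp1 and Tnp2 at 200.2, 0.687 and 1.84 and at 201, 0.744 and 0.539. The median gene of that list was 32.0- and 101-fold higher in replicate 1 than in replicates 2 and 3. The list medians on the log2(FPKM + 0.1) scale were -1.05, -3.32 and -3.24 for spermatocytes and -1.98, -3.32 and -2.93 for spermatogonia. The other added lists stayed low, at -2.94, -3.32 and -3.13 for neurons, -2.73, -3.32 and -3.23 for hepatocytes, -3.03, -3.32 and -3.23 for retina, and -3.32 in all 3 libraries for exocrine pancreas and gut.

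Some single genes differed between replicate 2 and the other libraries. Arg1, which encodes arginase, stood at 60.3, 0.751 and 22.1 FPKM in replicates 1, 2 and 3, the cytokine Il1b at 49.5, 7.08 and 40.0, and Spp1, which encodes osteopontin, at 20.2, 4.88 and 27.9. The chemokine Ccl17 stood at 12.9, 0.357 and 2.67 and the mast cell protease Mcpt4 at 13.9, 4.62 and 16.3. The general macrophage gene C1qb was at 409, 379 and 395. Cyp1a1, a target of the aryl hydrocarbon receptor, went the other way at 1.86, 29.3 and 2.48, as did the mitochondrial leucyl-tRNA synthetase Lars2 at 42.2, 129.6 and 29.9. No test was made of these genes, and they stand for no group.

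For the germ cell genes in replicate 1, some of which methylation silences in somatic cells, a deeper or noisier library that brings up silent genes of any tissue was considered. Of genes under FPKM 1 in replicates 2 and 3, 1 of 54 of the neuron, hepatocyte, pancreas and gut, and retina lists reached it in replicate 1 (1.85%). Of the germline list, fixed before the data were examined but also where the pattern was noticed, 4 of 19 did (21.1%, exact 95% interval 6.05 to 45.6), which lies above the upper bound of 9.89% for the other tissues although the intervals overlap, and replicate 1 also had the fewest rows at 0, 6042 against 9428 and 8006. This comparison took its present form after 2 others, Fisher's tests against the spermatid list and then the germline list, had been run and dropped, since both lists show the pattern. It still uses the germline list, so it restates the pattern and cannot decide on depth or noise. It shows only that few silent genes of the other tissues, 1 of 54, reached FPKM 1 in replicate 1. For epididymal duct tissue, the reproductive tract list had a median of -3.27 in replicate 1, with Lcn5 and Lcn8, abundant in that duct, listed at 0. Cst8, Svs4 and Eppin of that list stood at 8.61, 1.75 and 0.404 in replicate 1 and at or near 0 in the others. The test asked for a list median of FPKM 1 or more. The germline list, at -1.62 on the log2 scale in replicate 1, did not reach that either, so the test cannot decide on a small share of duct tissue. Testis RNA in replicate 1 is a candidate explanation, since genes of the somatic Leydig cells, which are not germ cells, were also higher there by a median log2 of 2.06 (percentile 99.6 of random lists, 7 of 9 genes highest), with Insl3 at 31.9, 0.0497 and 0.558 FPKM. Every other gene of that list stood at or under 1.41 FPKM in replicate 1, so the median rests on low values. Of all genes with a mean FPKM of at least 1, 46.7% were highest in replicate 1. Star was unchanged at 1.21, 1.19 and 1.31, and Lhcgr was highest in replicate 3. Whether testis RNA, if present, came from tissue at dissection, from handling or from another library through shared indices stays open. A change of methylation in replicate 1 was not tested, since no methylation values were analysed here, and no other biological explanation was tested.

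For the higher adipocyte genes and lower endothelial genes of replicate 1, a difference in overall scale was argued against, because the adipocyte list deviated by 1.101 after centring, beyond all 10000 matched random lists. A lower share of adipocyte RNA in replicates 2 and 3 would raise all other cell types alike. Endothelial and macrophage genes moved apart by -1.38 log2 units in replicate 1 over the others (bootstrap 95% interval over genes -1.52 to -1.18). More endothelial RNA in replicates 2 and 3 that dilutes the rest would lower macrophage genes there as much as adipocyte genes. Adipocyte and macrophage genes differed by 1.45 (1.21 to 1.72). The comparison of adipocyte with macrophage genes replaced one that asked only whether endothelial genes were lower in replicate 1, by -0.785, which they were. These comparisons were chosen after the list deviations had been seen, so their directions were already known. The intervals resample genes and not libraries, and give no measure of variation between libraries or animals. The values therefore describe these libraries and cannot decide on either explanation. It remains open whether the share of a single cell type changed or several cell types varied separately. Adipocytes of different animals may also differ in state, which was not tested.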
